A study of Arabidopsis thaliana with 12 samples.

How the data were processed

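Messenger RNA was sequenced from the third and the fourth rosette leaves of Arabidopsis thaliana, in 4 groups of 3 libraries. The groups were wild-type Col leaves without salt (mock), Col leaves with NaCl, and the same 2 treatments in overexpressor line #1 of ERF34. Per the labels' protocols, the transgene held the coding sequence of ERF34 behind the CsVMV promoter with GFP at its N-terminus. Salt-treated leaves were detached at 16 DAE, an abbreviation that the labels do not spell out, and floated for 1 day on 3 mM MES buffer (pH 5.8) with 100 mM NaCl at 22 °C with 16 h of light and 8 h of dark. The sample records list the same leaf age, buffer, temperature and light for the mock libraries, with no NaCl and no days of treatment. Whether mock leaves were detached and floated for 1 day is not stated in the sources used here. Differences between salt and mock leaves can therefore include effects of detachment and of 1 day of floating. The labels call the replicates independent and biological.

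Per the labels' protocols, libraries were made from 2 µg of RNA with an integrity number above 7.8, using poly(A) selection and a strand-specific Illumina TruSeq kit. The submitters' processing notes name TopHat, Cufflinks and the TAIR10 genome, with no versions. The deposited counts per gene are whole numbers and were not normalised. Their file is named for HTSeq, and the version and strand setting of the counting are not given in the sources used here. The authors also deposited TMM-normalised signal values. Each column of these equals the count column divided by 1 constant per library, so this signal holds no information beyond the counts except the scaling, and it was used only as an alternative input.

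The counts covered 33597 named genes, of which 24819 had at least 1 count. Another 7 entries without a gene name held 0.382% to 0.897% of a library's counts and were left out of library totals and tests. Library totals over named genes were 14301312 to 18398594 in wild type and 10425430 to 12704898 in the overexpressor. A count of 0 in a group of 3 libraries allowed up to 0.0641 counts-per-million (CPM) in wild-type mock, 0.0606 in wild-type salt, 0.0834 in overexpressor mock and 0.0812 in overexpressor salt, taking 3 counts over the group as the limit. Such limits and counting intervals cover counting error only. Where a group had 0 counts, a fold was computed against that limit. Gene identifiers were matched to a reference gene table of assembly TAIR10.1, which held 32835 of them, and coordinates are those of TAIR10.1. In the file 15 gene names were bare numbers, and such genes are named here by their locus identifier. Of the 115 named genes with a position, 21 overlapped another gene on the opposite strand and 5 on the same strand, and their counts can include reads of the neighbour if counting did not use strand.

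Genes were tested in R 4.3.3 with the robust quasi-likelihood F test of edgeR 4.0.16 on the deposited counts, with TMM factors, edgeR's filter on low counts by group (18886 genes tested) and 1 model of the 4 groups with 8 residual degrees of freedom and a common biological coefficient of variation of 0.249. The 5 contrasts were salt against mock in each genotype, overexpressor against wild type in each treatment, and the interaction of genotype with salt. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. Fold changes are those of this model. Their standard errors (SE) were computed as the absolute log2 fold change over the square root of the F value. They are rough where a group had few counts. Levels are CPM with TMM-scaled library sizes, as mean ± SD. All adjusted p-values for genes are from edgeR unless another tool is named. The 2 salt contrasts share no library, nor do the 2 genotype contrasts.

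The text names ERF34 in every comparison. It also names RD29A, ERD10, RD29B, SAG12, ORE1, NAP and NYE1, and for each comparison the 5 genes with the largest rise and the 5 with the largest fall. These had to be called, to reach 5 CPM in the higher group and to have every library of one group beyond every library of the other. For the interaction the rule asked for 3 genes each way without the last condition, and no gene qualified. From each gene list with at least 2 called members, up to 3 called members with the largest change and at least 1 CPM in the higher group were eligible. The 24 lists held 359 genes, and the antioxidant list also held genes tied to reactive oxygen, such as the respiratory burst oxidase gene RBOHF. PRODH1, SIRK and DVR were left out because their identifier and symbol disagreed in the reference, and 334 of the remaining 356 genes were tested. The lists were dehydration and late embryogenesis genes, abscisic acid synthesis and signalling, CBF/DREB factors, ion homeostasis, osmolytes, senescence markers and regulators, chlorophyll breakdown, chlorophyll synthesis, light harvesting and photosystems, ethylene, jasmonate, salicylate and defence, antioxidants, autophagy, heat shock, anthocyanin and flavonoid synthesis, glucosinolates, aquaporins, cell wall, relatives of ERF34, the circadian clock, guard cells with epidermis and trichomes, vascular tissue, and root, flower and meristem. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and again with an estimated correlation, adjusting over the 24 lists of a comparison. The groups, the models, the lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the alternatives and the tests of explanations that are named as later ones.

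Alternatives were the scaling factors of DESeq2, upper quartile factors, other filters on low counts, the Wald test of DESeq2 1.42.0, limma with trend on log2 of the authors' TMM values plus 1, a fold threshold, the replicate number as a block, only the 2 groups compared, and each library left out in turn. Counts thinned to 10425430 per library, the block fitted in 2 groups only and the block within each genotype for the interaction were chosen after the data were seen, as were the block for the similarity of fold changes and the left-out libraries for the medians of salt genes. The labels number the replicates 1 to 3 in each group without saying that a number marks a shared batch. Deviations of same-numbered libraries from their group means correlated at 0.31 to 0.40 between wild-type mock and salt, at 0.13 to 0.27 between overexpressor mock and salt, and at 0.27 to 0.73 between the genotypes in mock, so the numbers were taken as pairing these samples, from the data alone. Between the genotypes in salt the correlations were 0.37, -0.02 and 0.53, so pairing there was left uncertain. A number that marked a shared batch in the other groups would pair these samples too, so blocked counts are given as well. Within groups no replicate duplicated another, since replicates of a group differed by a chi-square of 11.4 to 52.4 per gene. The tests were tried on simulated counts for the real genes, with 200 genes changed in each of 3 simulations. At a 4-fold change, edgeR recovered 76.6% of the changed genes for the genotype contrast in salt and 52.3% for the interaction. At a 2-fold change it recovered 22.2% and 2.65%. In these simulations DESeq2 made up to 35 wrong calls in salt, 33 for the interaction and 23 in mock, where no gene was changed. For edgeR the highest numbers were 3, 4 and 0. The larger counts of DESeq2 below can therefore hold more false calls. Genotype cannot be told apart from the order of libraries, because the library numbers were 7 to 12 in wild type and 31 to 36 in the overexpressor. Figures were drawn with matplotlib 3.10.9.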

Results

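Transcripts were counted in 12 libraries from Arabidopsis rosette leaves, 3 each from wild-type mock leaves, wild-type leaves in NaCl, ERF34 overexpressor mock leaves and ERF34 overexpressor leaves in NaCl. The series asks whether ERF34, a transcription factor of the AP2/ERF family, holds back the leaf senescence that salt brings on, by way of salt-responsive genes. Total counts over named genes were 15389027, 16249983 and 16704329 in wild-type mock, 14301312, 17274608 and 18398594 in wild-type salt, 12704898, 10425430 and 12402241 in overexpressor mock, and 12358362, 11361715 and 12177909 in overexpressor salt. Every overexpressor library was thus shallower than every wild-type library. All means below are given ± SD over n = 3 libraries in counts-per-million (CPM).

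Salt separated the libraries more than genotype did. The first principal component held 57.2% of the variance, with mock libraries at -87.9 to -44.3 and salt libraries at 35.6 to 89.0. Within the salt libraries, the overexpressor stood at 35.6 to 56.3 and wild type at 72.2 to 89.0. The second component held 13.6%, and in each group the library of replicate 2 had the lowest value of the 3. Genes encoded in the plastid took 0.401 ± 0.0842% of counts in wild-type mock, 0.294 ± 0.119% in wild-type salt, 0.307 ± 0.0895% in overexpressor mock and 0.380 ± 0.183% in overexpressor salt.

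**Figure D1:**
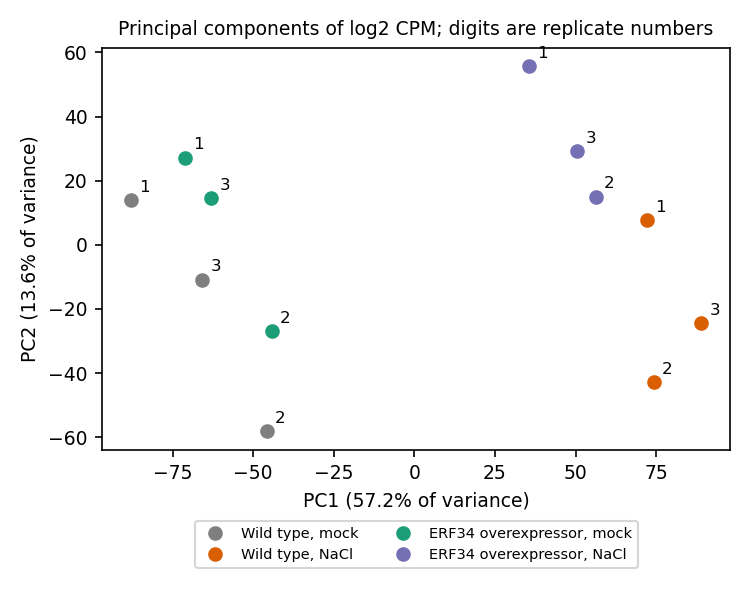
Principal components of log2 CPM for the 12 libraries, with the first component (57.2% of the variance) on the x axis and the second (13.6%) on the y axis, coloured by group and numbered by replicate. Mock libraries lie at -87.9 to -44.3 and salt libraries at 35.6 to 89.0 on the x axis.

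ERF34 (AT2G44940; TAIR10.1 chromosome 2, 18537177 to 18538479, plus strand, 1 exon) was at 8.83 ± 5.53 CPM in wild-type mock and 1051 ± 46.0 CPM in overexpressor mock, a 119-fold difference (log2 6.89, SE 0.603, adjusted p = 0.00254). In salt it was at 13.0 ± 6.14 CPM in wild type and 935 ± 144 CPM in the overexpressor, 71.7-fold higher (log2 6.16, SE 0.582, adjusted p = 0.00154). Reads from the coding sequence of the transgene count to this gene. Salt gave a log2 fold change of 0.56 in wild type (adjusted p = 0.379) and -0.17 in the overexpressor (adjusted p = 0.829), and neither was called. The mock difference was not called when only the mock libraries were fitted (log2 6.91, adjusted p = 0.0820).

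**Figure D2:**
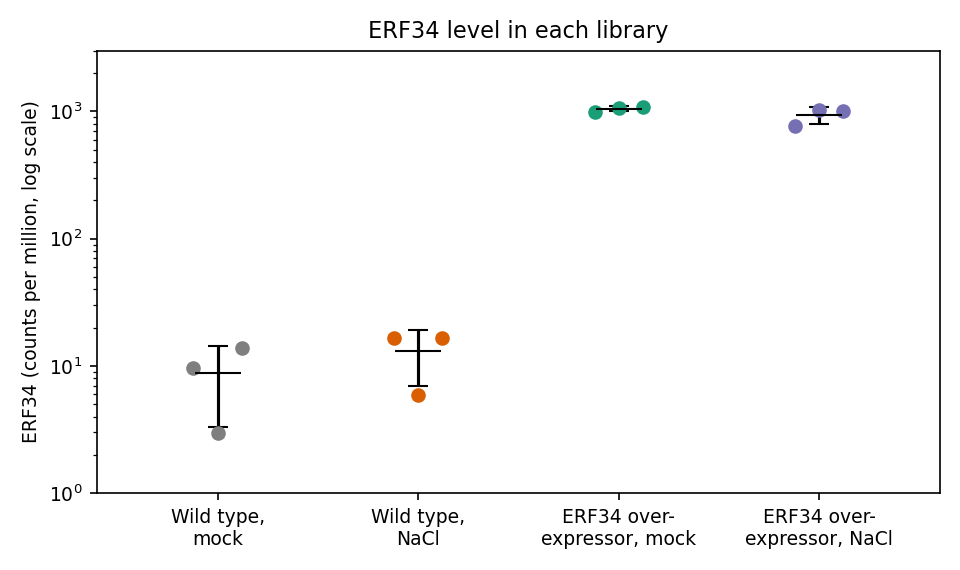
ERF34 level in each library on a log axis in CPM, by group, with the mean as a dash and bars of 1 SD. The 6 overexpressor libraries lie between 769 and 1082 CPM and the 6 wild-type libraries between 2.96 and 16.7 CPM.

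In wild-type leaves, the salicylate and defence list was called higher with salt (adjusted p = 9.85e-09, but adjusted p = 0.782 with an estimated correlation) and the light harvesting list lower (adjusted p = 2.67e-08, but adjusted p = 0.836 with an estimated correlation). As the labels do not say whether mock leaves were detached and floated for 1 day, the salt contrasts can include effects of detaching and floating the leaves. ALD1, which acts in the synthesis of the immune signal pipecolic acid, went from 0.517 ± 0.361 to 84.8 ± 4.23 CPM, a 162-fold rise (log2 7.34, SE 0.517, adjusted p = 1.78e-05). FMO1, which acts in the same pathway, rose 52.4-fold to 221 ± 27.4 CPM (adjusted p = 0.000111). ACS2, an enzyme that makes the precursor of ethylene, rose 36.0-fold from 7.42 ± 6.56 to 268 ± 78.8 CPM (adjusted p = 0.000251). Without wild-type mock replicate 2 the log2 fold changes of these genes were 8.01, 6.33 and 6.19, against 7.34, 5.71 and 5.17. Of 18886 genes tested, 7814 were called (41.4%), 3833 higher and 3981 lower with salt. Among the 334 list members tested, 160 were called. Counts of called members in single lists below are to be read beside these totals, and some lie under the share over all genes. With the replicate number as a block, 9650 genes were called. With only the wild-type libraries fitted the count was 6713, or 8469 with the block. Upper quartile scaling called 3311 higher and 4534 lower.

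Of the 5 largest rises in wild type by the fixed rule, 4 were in genes with no count in mock leaves. AOX1B, an alternative oxidase, was at least 799-fold higher in salt (51.2 ± 21.7 CPM, adjusted p = 0.000405). AT4G14368 was at least 575-fold higher, AT2G31860, annotated as a transcribed pseudogene, at least 542-fold higher, and IDL1, which encodes a small secreted peptide, at least 391-fold higher. The gene sks8 went from 0.0851 ± 0.0987 to 259 ± 85.9 CPM (log2 11.42, SE 0.793, adjusted p = 1.64e-05). The largest falls were in AT4G01390 (93.9-fold), in HAK5, a high-affinity potassium transporter (74.0-fold, from 6.66 ± 2.76 to 0.0838 ± 0.0457 CPM, adjusted p = 2.47e-05), and in AT1G15380 (27.1-fold). AT1G16390 fell 23.0-fold and RL6, a small MYB-related factor, fell 20.9-fold. On the log2 scale, sks8 was at 12.63 and AT4G01390 at -5.96 (against -6.55) without wild-type mock replicate 2, and AT4G01390 was at -7.78 and AT1G15380 at -5.61 (against -4.76) without wild-type salt replicate 3. AT4G14368 was at 23.7, 11.6 and 75.4 CPM in the salt libraries, and without replicate 3 its fitted log2 fold change, which depends on the prior count, was 10.92 against 12.03.

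In the salicylate and defence list, 16 of 18 tested members were higher in salt and 0 lower (17 higher adjusted over the list alone). PR2, a secreted glucanase, rose 31.7-fold to 756 ± 261 CPM (adjusted p = 7.25e-05). The median member changed by 2.39 on the log2 scale. In the ethylene list, 8 of 23 members rose and 3 fell, the same counts as adjusted over the list alone. Besides ACS2, the synthase genes ACS7 and ACS8 rose 14.6-fold and by 4.12 on the log2 scale. The jasmonate list had 5 of 23 members higher and 1 lower, also adjusted over the list alone. VSP2, a vegetative storage protein, rose 27.4-fold (1.14 ± 1.00 to 31.3 ± 33.2 CPM), TAT3 rose 13.2-fold, and the defensin gene PDF1.2A fell 6.84-fold. As lists, ethylene (adjusted p = 0.198) and jasmonate (adjusted p = 0.344) were not called, though jasmonate was without wild-type mock replicate 2 (0.0470). Without that library the log2 fold changes of VSP2, TAT3 and PDF1.2A were 5.74, 5.26 and -2.05, against 4.77, 3.73 and -2.77, and without wild-type salt replicate 2 that of VSP2 was 3.41.

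Of 44 tested genes of light harvesting and the photosystems, 31 fell in wild type and 0 rose (33 fell adjusted over the list alone). LHCB2.3 fell 3.63-fold, LHCB4.3 fell 2.74-fold from 118 ± 12.9 to 43.1 ± 3.73 CPM, and PSAN, a subunit of photosystem I, changed by -1.13 on the log2 scale. The median member changed by -0.55 on the log2 scale. Several LHCB and RBCS genes are near-identical copies, and how the counting divided reads between them is not given. In the chlorophyll synthesis list, 7 of 15 members fell and 2 rose, the same adjusted over the list alone. GUN4 fell 2.34-fold and HEMA1 fell 2.18-fold, whereas GSA1 rose 2.12-fold. In the chlorophyll breakdown list, NYE2, a STAY-GREEN gene, rose 3.28-fold and 3 of 7 members fell, with NYC1, a chlorophyll b reductase, 3.13-fold lower and RCCR 2.11-fold lower. These counts were the same adjusted over the list alone. NYE1 changed by -0.26 on the log2 scale (adjusted p = 0.511). Neither chlorophyll list was called (adjusted p = 0.344 for each).

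Among senescence markers and regulators, 11 of 28 tested members rose with salt in wild type and 5 fell, the same adjusted over the list alone, and the list was not called (adjusted p = 0.106), though it was without wild-type salt replicate 1 (0.0286). DIN2, a beta-glucosidase gene, rose 26.9-fold from 1.02 ± 0.671 to 27.4 ± 14.2 CPM. WRKY75, a transcription factor, rose 11.5-fold (log2 3.53, or 4.62 without wild-type mock replicate 2) and SAG29, a sugar transporter gene, fell 11.2-fold (log2 -3.49, or -4.12 without wild-type salt replicate 3). The NAC factors ORE1 (log2 0.48, adjusted p = 0.378) and NAP (log2 0.60, adjusted p = 0.238) were not called, though NAP was without wild-type salt replicate 1 (0.0456). SAG12, a cysteine protease gene widely used as a marker of late senescence, had 0 counts in all 12 libraries, which allows up to 0.168 to 0.293 CPM per library.

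Of the dehydration and late embryogenesis list, 5 of 17 members rose in wild type and 0 fell, the same adjusted over the list alone. EM1 rose from 0.0644 ± 0.112 to 5.17 ± 1.28 CPM, with a count ratio of 81.0 (95% counting interval 27.4 to 395). Its mock counts all lay in replicate 2, and without that library the fitted log2 fold change, which depends on the prior count, was 9.18 against 6.15. RD29B rose 9.46-fold (log2 3.24, SE 0.526, adjusted p = 0.000815) and RD20, a caleosin, rose 4.29-fold. RD29A (log2 0.97, adjusted p = 0.170) and ERD10 (log2 -0.15, adjusted p = 0.796) were not called, though RD29A was without wild-type mock replicate 2 (0.0437). In the abscisic acid list, 4 of 12 members rose and 2 fell, also adjusted over the list alone. The phosphatase genes HAI1 and HAI2 rose 12.2-fold and 4.76-fold, and CYP707A1, which breaks the hormone down, rose 4.56-fold. In the CBF/DREB list, DREB2B rose 4.19-fold. CBF1 was called 6.24-fold lower (log2 -2.64, adjusted p = 0.0496, or 0.0505 with the replicate number as a block), at 1.85, 7.48 and 36.1 CPM in the mock libraries and 1.64, 2.06 and 3.53 CPM in the salt libraries, which overlap. Its log2 fold change was -0.94 without wild-type mock replicate 3 (adjusted p = 0.392), and the call was also lost without salt replicate 1 (0.129), 2 (0.124) or 3 (0.0805), with a range over all alternatives of 0.00849 to 0.392. Adjusted over the list alone, 1 of its 6 members was higher and 0 lower. The median of the CBF/DREB list was 0.43 on the log2 scale and its mean -0.06. Its adjusted p was 0.674, against 0.106 for dehydration and 0.336 for abscisic acid. The dehydration list was called without wild-type mock replicate 2 (0.0143) or salt replicate 1 (0.0406).

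Of 11 ion homeostasis genes, 0 rose and 3 fell (2 adjusted over the list alone). They were HAK5, the vacuolar proton pump AVP1 (1.70-fold) and the calcium sensor CBL10 (1.47-fold). In the osmolyte list, P5CS1, an enzyme of proline synthesis, rose 1.89-fold and RS5, a raffinose synthase, rose by 0.49 on the log2 scale, out of 6 members (0 adjusted over the list alone). Neither list was called (adjusted p = 0.344 and 0.518). Aquaporins were called lower as a list (adjusted p = 0.0213, but adjusted p = 0.836 with an estimated correlation, and 0.0517 without wild-type salt replicate 2). Of 17 aquaporins, 8 fell and 1 rose, the same adjusted over the list alone. PIP2;2 fell 3.66-fold, TIP2;2 fell 3.14-fold and PIP1;1 fell 2.06-fold. The cell wall list was called higher (adjusted p = 0.00934, but adjusted p = 0.836 with an estimated correlation), with 7 of 15 members higher and 0 lower, also adjusted over the list alone. XTH4 rose 2.95-fold, the cellulose synthase gene CESA6 rose 2.08-fold and CSI1 rose 1.80-fold.

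No other list was called in wild type (adjusted p from 0.344 to 0.878). Of 17 genes in the antioxidant list, 2 rose and 3 fell (2 and 2 adjusted over the list alone). RBOHF, a respiratory burst oxidase gene and not an antioxidant one, was 3.73-fold higher. GR1 was 1.74-fold higher and the catalase CAT2 2.35-fold lower. The antioxidant median was -0.06 and the mean 0.07 on the log2 scale. Of 15 autophagy genes, 3 rose and 6 fell, also adjusted over the list alone, with ATG8H 1.84-fold higher, ATG8F 1.92-fold lower and ATG8C 1.79-fold lower. Of 7 heat shock genes, HSFA2 rose 3.28-fold, HSP90.1 rose 2.62-fold and HSP18.2 fell 1.79-fold, the same calls as adjusted over the list alone. In the glucosinolate list, CYP79B2 rose 3.55-fold and 4 of 14 members fell, including MYB34 (3.23-fold) and CYP79B3 (2.27-fold), the same adjusted over the list alone. Without wild-type mock replicate 2 the log2 fold change of CYP79B2 was 2.58, against 1.83, and that of MYB34 was -0.97, against -1.69, and not called (adjusted p = 0.143). Of 13 anthocyanin and flavonoid genes, 1 was called, also adjusted over the list alone. It was the MYB factor PAP2 (log2 -3.25, adjusted p = 0.00396), named after its value was seen. The anthocyanin median was 0.27 although the list test pointed down. Among 4 tested relatives of ERF34, ERF35 fell 3.64-fold (log2 -1.86, or -2.63 without wild-type salt replicate 2) and ERF39 fell 3.18-fold, also adjusted over the list alone. Of 11 clock genes, 4 fell (3 adjusted over the list alone), with GI 2.29-fold, PRR7 2.27-fold and PRR5 1.67-fold lower. Markers of other leaf tissues included MYB60 (3.33-fold lower) and ATML1 (2.29-fold lower) of 5 guard cell and epidermis genes, and SEOR1 (2.12-fold lower) and SUC2 (1.36-fold lower) of 5 vascular genes. Both pairs were called adjusted over the list alone too. PI, the single tested member of the root, flower and meristem list, was not called, nor was it adjusted over the list alone.

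In overexpressor leaves, the salicylate and defence list was also called higher with salt (adjusted p = 6.99e-07, but adjusted p = 0.557 with an estimated correlation). ALD1 rose 42.7-fold from 1.11 ± 0.741 to 48.6 ± 16.4 CPM (log2 5.42, SE 0.473, adjusted p = 0.000187, or log2 6.13 without overexpressor mock replicate 3), FMO1 rose 19.1-fold and PR2 rose 9.74-fold to 284 ± 68.0 CPM. ACS2 rose 20.1-fold to 128 ± 64.5 CPM, ACS8 rose 13.3-fold and ACS7 rose 6.54-fold. Salt changed 3449 genes (18.3%), 1835 higher and 1614 lower. With the replicate number as a block, 5327 genes were called, and with only the overexpressor libraries fitted, 2227. Without overexpressor mock replicate 1 the count was 1519, without overexpressor mock replicate 3 it was 1628, and without overexpressor salt replicate 2 it was 2116.

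The largest rises in the overexpressor were again in AOX1B (at least 400-fold, 33.4 ± 18.7 CPM), AT2G31860 (at least 272-fold) and sks8 (log2 10.37, SE 0.783, adjusted p = 0.000107, or log2 11.55 without overexpressor mock replicate 1). They also included AT3G54530 (at least 385-fold) and AT3G54520 (at least 259-fold), neighbours on chromosome 3. OSM34, an osmotin gene, was at least 69.2-fold lower in salt (5.62 ± 3.67 CPM in mock, adjusted p = 0.0194). KTI1, a protease inhibitor gene, fell with a count ratio of 151 (95% counting interval 51.4 to 736), and AT1G15380 fell with a ratio of 156 (42.8 to 1294). HAK5 fell 101-fold and AT4G01390 fell 65.6-fold (log2 -6.04, or -6.63 without overexpressor salt replicate 2).

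The salicylate and defence list had a median of 1.82 on the log2 scale in the overexpressor, with 12 of 18 members higher and 0 lower, also adjusted over the list alone. The dehydration list was called higher (adjusted p = 0.00599, but adjusted p = 0.811 with an estimated correlation), with 3 of 17 members higher (8 adjusted over the list alone). EM1 rose with a count ratio of 164 (95% counting interval 29.0 to 6505), RD22 rose 2.87-fold and RD20 rose 2.44-fold. The mock count of EM1 lay in replicate 2, and without that library its fitted log2 fold change was 9.07 against 6.99. RD29B was at 0.494 ± 0.252 CPM in mock and 1.49 ± 0.487 CPM in salt (log2 1.62, adjusted p = 0.0514, or 0.0480 with the replicate number as a block). RD29A (log2 0.97, adjusted p = 0.227) and ERD10 (log2 0.63, adjusted p = 0.325) were not called. The cell wall list was called higher (adjusted p = 2.73e-05, but adjusted p = 0.557 with an estimated correlation), with 7 of 15 members higher (13 adjusted over the list alone), among them XTH4 (3.83-fold), CESA4 (2.31-fold) and CESA6 (1.78-fold).

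Chlorophyll breakdown was called lower as a list in the overexpressor (adjusted p = 0.0346, but adjusted p = 0.747 with an estimated correlation), and autophagy likewise (adjusted p = 0.0346, but adjusted p = 0.811 with an estimated correlation). With the replicate number as a block, both had an adjusted p of 0.05002 and were not called. Without overexpressor mock replicate 3 the values were 0.0666 and 0.0647, and without overexpressor salt replicate 1 they were 0.117 and 0.241. NYC1 fell 2.27-fold and RCCR 1.65-fold, 2 of 7 members, also adjusted over the list alone. In the autophagy list, ATG8G fell 1.67-fold, ATG8I 1.63-fold and ATG8B 1.55-fold, 3 of 15 members (7 adjusted over the list alone). NYE1 was not called (log2 -0.64, adjusted p = 0.165).

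Light harvesting genes had 4 of 44 members lower and 0 higher in the overexpressor (1 lower adjusted over the list alone). The list was not called (median log2 -0.14, adjusted p = 0.0563), though it was without overexpressor mock replicate 1 (8.77e-05) or salt replicate 3 (0.00433). LHCB4.3 fell 2.38-fold, PSAN 1.45-fold and RCA, the activase of Rubisco, 1.44-fold. In chlorophyll synthesis, 3 of 15 members rose and 0 fell, also adjusted over the list alone. They were HEMB1 (1.96-fold), CHLG (1.69-fold) and CHLI1 (1.45-fold). Of 28 senescence genes, 5 rose and 2 fell (5 and 3 adjusted over the list alone), with RNS1, a ribonuclease gene, 4.98-fold higher, SEN1 10.5-fold lower (log2 -3.39, or -4.27 without overexpressor salt replicate 2) and GLN1;4 2.97-fold lower. ORE1 (log2 -0.65, adjusted p = 0.303) and NAP (log2 -0.39, adjusted p = 0.510) were not called. Of 23 ethylene genes, 4 rose and 0 fell (4 and 1 adjusted over the list alone). Of 23 jasmonate genes, 3 rose and 1 fell, also adjusted over the list alone, with the close copies VSP2 16.8-fold (0.542 ± 0.537 to 8.66 ± 8.71 CPM) and VSP1 12.7-fold higher and PDF1.2A 6.15-fold lower. The log2 fold change of VSP2, 4.07 with all libraries, was 3.45, 4.96 and 2.84 without overexpressor mock replicate 1, mock replicate 2 and salt replicate 1. VSP2 was not called without any of these (adjusted p = 0.140, 0.0680 and 0.160), nor without mock replicate 3 (0.132) or salt replicate 3 (0.0585), with a range over all alternatives of 0.0106 to 0.160. VSP1 was at 4.28 without mock replicate 2, against 3.67, and PDF1.2A at -3.90 without salt replicate 1, against -2.62. The ethylene and jasmonate medians were -0.00 and -0.07 although their list tests pointed up.

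In the abscisic acid list, HAI2 rose 5.14-fold, CYP707A1 3.41-fold and ABI2 1.66-fold, and 1 of 12 members fell, also adjusted over the list alone. That member was ABF4 (log2 -0.69), named after its value was seen, as were DREB2B (log2 1.92) of 6 CBF/DREB genes and P5CS1 (log2 1.63) of 6 osmolyte genes, which were the members called in their lists (1 and 2 adjusted over the list alone). Of 11 ion homeostasis genes, HAK5 and the proton pump AHA2 (1.89-fold) fell and 0 rose (3 fell adjusted over the list alone). Of 17 genes in the antioxidant list, 1 rose and 5 fell, also adjusted over the list alone. The gene that rose was the oxidase gene RBOHF (2.72-fold). The superoxide dismutases CSD2 and CSD1 were 3.23-fold and 2.23-fold lower. HSFA2 rose 6.72-fold, HSP90.1 2.99-fold (19.4 ± 2.51 to 58.0 ± 45.5 CPM), and HSP18.2 fell 2.02-fold, of 7 heat shock genes (3 higher and 1 lower adjusted over the list alone). The log2 fold change of HSP90.1 was 1.58 and, without overexpressor salt replicate 2, 0.71 (adjusted p = 0.0387), and the call was lost without overexpressor mock replicate 1 (0.101), 2 (0.0551) or 3 (0.0948), with a range over all alternatives of 0.00280 to 0.101. Of 17 aquaporins, PIP2;6 rose 1.65-fold and 3 fell, also adjusted over the list alone, with PIP2;2 2.21-fold and TIP2;2 2.14-fold lower. The members called in 4 further lists, PAP2 (log2 -3.01), PRR7 (log2 -0.79), XCP2 (log2 0.93) and PI (log2 4.70), were named after their values were seen. Adjusted over the list alone, the anthocyanin, clock, vascular and root lists had 1 lower, 1 lower, 1 higher with 2 lower, and 1 higher. The anthocyanin median was 1.34 although its list test pointed down. By edgeR, 0 members were called, also adjusted over the list alone, in the glucosinolate list (4 of 14 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma), the ERF34 relatives (1 of 4, 0 and 0) and the guard cell and epidermis list (1 of 5, 0 and 0). List tests not given above had an adjusted p from 0.0861 to 0.966.

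Across genes, which are not independent replicates, the salt responses of the 2 genotypes had a Pearson correlation of 0.836 and a Spearman correlation of 0.782. Of the 1835 genes higher with salt in the overexpressor, 1577 were higher in wild type too (372 for independent lists), and of the 1614 lower genes, 1411 were lower in wild type (340 for independent lists). For the 3833 genes raised by salt in wild type, the median log2 fold change was 1.09 in wild type and 0.574 in the overexpressor. For the 3981 lowered genes it was -0.913 and -0.474. The fold change was smaller in the overexpressor for 88.1% of the raised and 92.4% of the lowered genes. The genes were chosen in wild type, which favours larger values there. In 20 simulations without a genotype effect the mean medians of raised genes were 1.23 and 1.09.

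**Figure D3:**
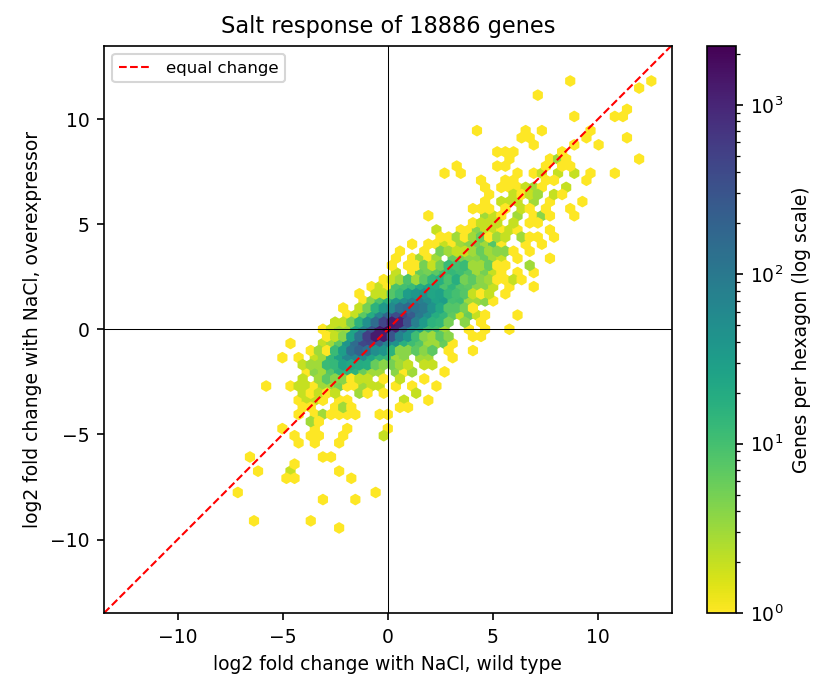
Salt response of 18886 genes, with the log2 fold change (NaCl over mock) in wild type on the x axis and in the overexpressor on the y axis; colour gives genes per hexagon on a log scale and the dashed line marks equal change. Most genes far from 0 lie between the x axis and the dashed line, and the Pearson correlation is 0.836.

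Without salt, besides ERF34, the boron transporter gene BOR5 was 3.56-fold higher (17.3 ± 3.88 to 61.5 ± 12.6 CPM, adjusted p = 0.0244), AT2G39530 was 3.27-fold and the myosin gene XIB 3.17-fold higher. AT2G16595 was 2.68-fold higher and AT1G58590, annotated as a non-coding RNA, 2.57-fold higher. MRD1 was 35.4-fold lower in the overexpressor (38.3 ± 3.86 to 1.06 ± 0.368 CPM, adjusted p = 2.26e-05). AT2G01422, a non-coding RNA, was 59.2-fold lower, AT5G24240 36.5-fold lower (log2 -5.19, adjusted p = 0.0368, or 0.0506 with the replicate number as a block), QQS, an orphan gene linked to starch content, 5.06-fold lower and the pseudogene AT2G07080 2.80-fold lower. MRD1 overlaps AT1G53490 (log2 -2.01) and AT5G24240 overlaps AT5G24230 on the other strand, and the strand setting of the counting is not given, so reads within such pairs are uncertain. AT5G24240 was at -6.37 without overexpressor replicate 1 (adjusted p = 0.0962) and -4.59 without overexpressor replicate 3 (0.142). In all, 19 genes were called, 12 higher and 7 lower. DESeq2 called 196, limma 29, and the fit of the mock libraries alone 4. That fit called 372 with the replicate number as a block (242 higher and 130 lower), and the model of all groups called 23 with it. The count was 3 without wild-type replicate 1 or overexpressor replicate 1 or 3, 4 without wild-type replicate 2 or 3, and 11 without overexpressor replicate 2.

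All 24 lists had 0 called members in mock by edgeR, although 23 of 334 members had an unadjusted p under 0.05, and DESeq2 called 5 and limma 0. Adjusted over the list alone, 1 osmolyte and 1 defence gene were higher, as were 4 cell wall genes with 1 lower. The salicylate and defence list was called higher (median log2 0.40, adjusted p = 0.00191, but adjusted p = 0.819 with an estimated correlation), with 15 of 18 members above 0. Light harvesting (median log2 -0.11, adjusted p = 0.00171, but adjusted p = 0.965 with an estimated correlation) and aquaporins (median log2 -0.33, adjusted p = 0.00196, but adjusted p = 0.819 with an estimated correlation) were called lower. The light harvesting call was lost without overexpressor replicate 1 (adjusted p = 0.679), and the defence call without wild-type replicate 1 (0.198) or overexpressor replicate 2 (0.0586). With the replicate number as a block, chlorophyll synthesis (0.0464), jasmonate (0.0416) and cell wall (0.0464) were called as well. The other lists had an adjusted p from 0.0575 to 0.985, and the CBF/DREB, ethylene and glucosinolate medians (-0.07, -0.03 and -0.01) lay below 0 although their tests pointed up. RD29A (log2 1.19, adjusted p = 0.675), ERD10 (0.32, 0.938), RD29B (1.00, 0.833), ORE1 (-0.06, 0.995), NAP (-0.48, 0.895) and NYE1 (0.23, 0.937) were not called.

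In salt, the senescence list was called lower in the overexpressor than in wild type (adjusted p = 7.56e-06, but adjusted p = 0.805 with an estimated correlation), with 2 of 28 members called. DIN2 was 37.1-fold lower (27.4 ± 14.2 CPM in wild type, 0.727 ± 0.454 CPM in the overexpressor, log2 -5.21, adjusted p = 0.00733, or log2 -5.80 without overexpressor replicate 3) and SAG13 was 5.10-fold lower (152 ± 72.1 and 29.9 ± 6.22 CPM, adjusted p = 0.0182). Of 17 antioxidant genes, 3 were called lower, the superoxide dismutase CSD1 2.06-fold, the ascorbate peroxidase APX1 1.83-fold and the glutathione reductase GR1 1.45-fold, and the list was not called (adjusted p = 0.114). Of 829 genes called, 390 were higher and 439 lower, whereas upper quartile scaling called 441 higher and 352 lower. The count was 45 without wild-type replicate 3, 60 without wild-type replicate 2, 77 without overexpressor replicate 3 and 347 without overexpressor replicate 2. It was 13 with only the salt libraries fitted and 1763 by DESeq2. With the replicate number as a block, the model of all groups called 2344 genes and the fit of the salt libraries alone 620.

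Among the largest differences in salt, the plastid-encoded genes psbT (7.79-fold) and ndhE (log2 2.54) were higher in the overexpressor, beside a plastid share of counts in salt of 0.294 ± 0.119% in wild type and 0.380 ± 0.183% in the overexpressor. In mock, where the share was 0.401 ± 0.0842% in wild type and 0.307 ± 0.0895% in the overexpressor, psbT was at 2.09 ± 1.02 and 5.85 ± 2.14 CPM and ndhE at 2.47 ± 0.794 and 5.29 ± 1.13 CPM, and neither was called (adjusted p = 0.557 and 0.653). Without wild-type salt replicate 1, psbT was 16.0-fold higher in salt, and the log2 fold changes of ndhE and AT4G13990 were 3.41 and 3.31, against 2.54 and 2.62. AT4G28780 was 6.97-fold higher, the serine carboxypeptidase-like gene SCPL7 6.70-fold (2.08 ± 0.436 to 14.0 ± 5.76 CPM, adjusted p = 0.0104) and AT4G13990 6.14-fold. AT5G41660 was at least 116-fold lower in the overexpressor, with 0 counts in all 6 overexpressor libraries, and was not called in mock (adjusted p = 0.103). The pseudogene AT3G60170 was lower with a count ratio of 280 (95% counting interval 49.9 to 11083) and KTI1 with a ratio of 95.5 (32.4 to 465). Without overexpressor salt replicate 3, which held the salt count of AT3G60170 in that genotype, its fitted log2 fold change was -9.74 against -7.70. That of KTI1 was -5.69 against -6.38 without wild-type salt replicate 2, where the call was lost (adjusted p = 0.102). The KTI1 call was also lost without wild-type salt replicate 3 (0.0944) or overexpressor salt replicate 1 (0.0773), 2 (0.0826) or 3 (0.112), with a range over all alternatives of 2.66e-06 to 0.112. AT2G01422 was 105-fold lower (log2 -6.72, or -8.27 without overexpressor salt replicate 2) and MRD1 78.5-fold lower (adjusted p = 8.00e-06). All 7 genes lower in mock were also lower in salt (0.163 for independent lists), and 9 of the 12 higher genes were higher (0.248 for independent lists). Of the other 3, AT2G39530 was lower in salt (log2 -0.96, adjusted p = 0.0433) and AT1G58590 and AT2G16595 were not called. Over all genes, the overexpressor effects in mock and in salt correlated at 0.211 (Pearson) and 0.148 (Spearman), and at -0.037 without wild-type mock replicate 2.

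Of 28 senescence genes, 0 were higher and 2 lower in overexpressor salt leaves (7 lower adjusted over the list alone), and 4 had a fold change above 0. The median was -0.67 on the log2 scale. NAP was at 77.6 ± 35.0 CPM in wild type and 27.9 ± 11.3 CPM in the overexpressor (log2 -1.47, SE 0.394, adjusted p = 0.0608), and was called by DESeq2 (0.00461) and without wild-type replicate 1 (0.0185). ORE1 was at 47.1 ± 16.4 and 20.7 ± 5.75 CPM (log2 -1.19, adjusted p = 0.132). NYE1 (log2 -0.15, adjusted p = 0.818), ERD10 (1.11, 0.163) and RD29B (-0.62, 0.429) were not called either, nor was RD29A (2.29-fold, 0.219). Light harvesting genes were called higher as a list (median log2 0.30, adjusted p = 6.71e-07, but adjusted p = 0.805 with an estimated correlation). Of the 44 members 43 lay above 0, and edgeR called 0 of them, also adjusted over the list alone (14 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma). The salicylate and defence list (median log2 -0.52, adjusted p = 0.0111, but adjusted p = 0.805 with an estimated correlation) and the jasmonate list (median log2 -0.85, adjusted p = 0.0111, but adjusted p = 0.842 with an estimated correlation) were called lower. All 23 jasmonate genes lay below 0 and 0 were called by edgeR, also adjusted over the list alone (1 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). In mock, too, only 2 of the 23 lay above 0 (median log2 -0.50, list adjusted p = 0.0637). For the interaction the jasmonate list was not called (adjusted p = 0.365), though it was without wild-type mock replicate 2 (0.00527) or overexpressor mock replicate 1 (0.0271). Whether its lower level was particular to salt therefore stays open.

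Osmolytes (adjusted p = 0.0472, but adjusted p = 0.805 with an estimated correlation) and chlorophyll synthesis (adjusted p = 0.0476, but adjusted p = 0.805 with an estimated correlation) were called higher and ethylene lower (adjusted p = 0.0476, but adjusted p = 0.814 with an estimated correlation). The osmolyte call was lost without wild-type replicate 1 (0.122) or overexpressor replicate 1 (0.0946). The ethylene call was lost without wild-type replicate 3 (0.254) or overexpressor replicate 1 (0.355) and with the factors of DESeq2 (0.0511). Chlorophyll synthesis lost its call with those factors (0.0502) and without wild-type replicate 1 (0.0802), wild-type replicate 3 (0.156), overexpressor replicate 1 (0.147) or overexpressor replicate 3 (0.0641). By edgeR 0 of its 15 members were called (1 higher adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). In 9 lists a single member was called, named after its value was seen. Higher were GOLS3 (log2 2.55; osmolytes), TIP2;2 (log2 0.69; aquaporins) and CESA1 (log2 0.45; cell wall). RD20 (log2 -1.24), HAI1 (log2 -2.09), NYE2 (log2 -1.70), ACO4 (log2 -1.22), PAD3 (log2 -2.26) and CYP79B2 (log2 -2.24) were lower. Adjusted over the list alone, the osmolyte and cell wall lists had 2 higher each, aquaporins 1 higher, dehydration 1 higher and 2 lower, antioxidants 3 lower, and the lists of HAI1, NYE2, ACO4, PAD3 and CYP79B2 1 lower each. The remaining 10 lists had 0 members called, also adjusted over the list alone. Over all 334 members, edgeR called 14, DESeq2 32 and limma 15, with 70 at an unadjusted p under 0.05. Lists not called had an adjusted p from 0.0632 to 0.998, and the anthocyanin (1.17) and vascular (0.21) medians were above 0 although their tests pointed down.

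Genes raised by salt in wild type were lower in overexpressor than in wild-type salt leaves, with a median log2 difference of -0.296, and genes lowered by salt were higher, with a median of 0.281. Simulations without a genotype effect, sharing the wild-type libraries in the same way, gave -0.0866 to -0.0495 and 0.0643 to 0.0831. The simulated genes varied independently of each other and without an effect of the replicate number, unlike the real libraries. The simulated ranges are therefore too narrow to serve as limits for unchanged groups. In mock the medians were 0.130 and -0.120, against 0.0606 to 0.0889 and -0.0868 to -0.0588 in the simulations. Without wild-type mock replicate 1 or overexpressor mock replicate 2 the mock median of the lowered genes was -0.0758 or -0.0798, within the simulated range, and without wild-type mock replicate 2 that of the raised genes was 0.200.

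The interaction asked whether salt acted differently in the 2 genotypes. By fold change alone, light harvesting genes fell less or rose more with salt in the overexpressor, with 44 of 44 above 0 and a median interaction of 0.41 on the log2 scale (list adjusted p = 5.96e-11, but adjusted p = 0.684 with an estimated correlation). Of these 44 members edgeR called 0, also adjusted over the list alone (8 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma). Aquaporins (16 of 17 above 0, median 0.56, adjusted p = 0.000848, but adjusted p = 0.642 with an estimated correlation) and chlorophyll synthesis (13 of 15, median 0.50, adjusted p = 0.00318, but adjusted p = 0.642 with an estimated correlation) were also called higher. Salicylate and defence genes were called lower, with 2 of 18 above 0 (median -1.11, adjusted p = 9.96e-06, but adjusted p = 0.642 with an estimated correlation). Senescence genes were called lower with 10 of 28 above 0 (median -0.53, adjusted p = 0.00458, but adjusted p = 0.895 with an estimated correlation), and lost the call without overexpressor salt replicate 1 (0.216). Ethylene genes were called lower with 6 of 23 above 0 (median -0.30, adjusted p = 0.0464, but adjusted p = 0.899 with an estimated correlation).

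No single gene was called for the interaction by edgeR, although 2580 had an unadjusted p under 0.05, and DESeq2 called 658 and limma 64. A share of 0.05 of the genes tested is 944, which leaves the shared deviations of same-numbered libraries aside. In simulations DESeq2 made up to 33 wrong calls for the interaction and edgeR up to 4. With the replicate number as a block within each genotype, an alternative chosen after the data were seen, edgeR called 99 genes, 14 higher and 85 lower. With the number as 1 block over all groups, which also pairs the genotypes in salt, it called 379 genes, 111 higher and 268 lower. The lowest adjusted p, 0.0530, was shared by AT1G02360 (log2 -3.00), AT2G39530 (-2.67), AT3G51330 (-2.23), RLP50 (-1.33) and RABA1e (-3.25), named after their values were seen. ERF34 (log2 -0.73, adjusted p = 0.725), RD29B (-1.62, 0.384), ORE1 (-1.13, 0.440) and NAP (-0.99, 0.475) were not called. Nor were RD29A (0.01, adjusted p = 1.00), ERD10 (0.78, 0.649) and NYE1 (-0.38, 0.792). Of the 334 list members, edgeR called 0, DESeq2 12 and limma 1, and 45 had an unadjusted p under 0.05. Adjusted over the list alone, 1 abscisic acid gene, 1 ion homeostasis gene, 2 senescence genes, 2 defence genes and 3 genes of the antioxidant list were lower. Without 1 library the count of called genes was 73 (without overexpressor salt replicate 1), 67 (wild-type salt replicate 1), 36 (wild-type mock replicate 2), 6 (overexpressor mock replicate 2) or 0. The ethylene list lost its call without wild-type mock replicate 1 (0.280) or 2 (0.0719), wild-type salt replicate 3 (0.287), overexpressor mock replicate 2 (0.0916) or 3 (0.142), or overexpressor salt replicate 1 (0.386). The other 18 lists had an adjusted p from 0.365 to 0.999, and the anthocyanin (1.19), antioxidant (0.05) and glucosinolate (0.01) medians were above 0 although their tests pointed down.

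**Figure D4:**
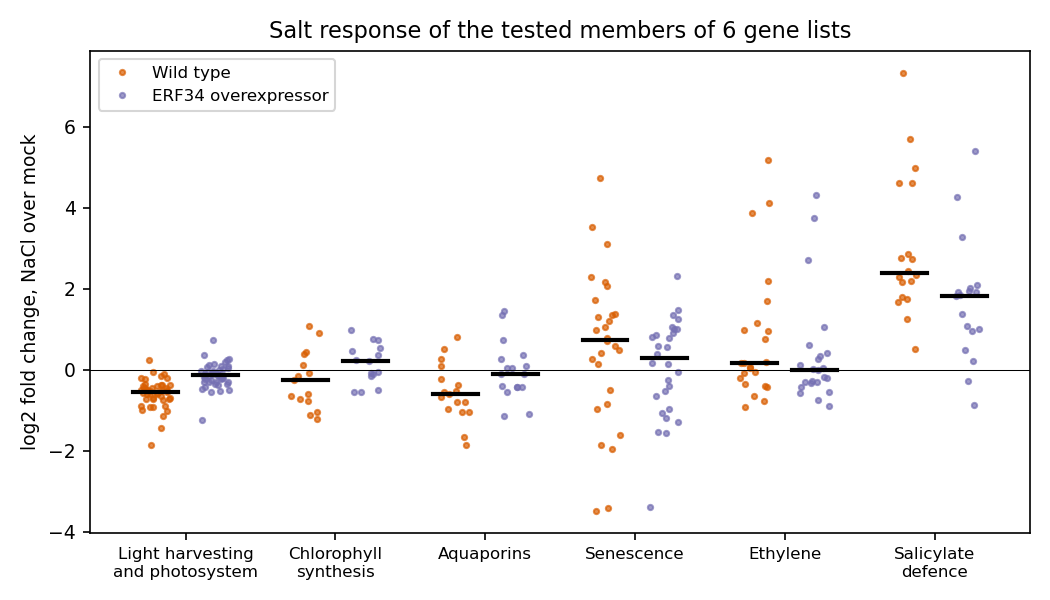
Salt response (log2 fold change, NaCl over mock, y axis) of every tested member of the 6 lists called for the interaction, 1 dot per gene, wild type in orange and overexpressor in purple, with the median as a bar. The medians of light harvesting are -0.55 in wild type and -0.14 in the overexpressor, and those of salicylate and defence 2.39 and 1.82.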

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

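The splits of the samples and the clock test of replicate numbers were planned. The other tests of explanations in this part were chosen only after the results were seen.

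The interaction test called 6 gene lists as differing in salt response between the genotypes, and none of these 6 calls held with an estimated correlation between genes (adjusted p from 0.642 to 0.899). The median interaction on the log2 scale was -0.53 for senescence genes, 0.50 for chlorophyll synthesis, 0.41 for light harvesting, -0.30 for ethylene, -1.11 for salicylate and defence, and 0.56 for aquaporins. In wild type the medians of the salt response were 0.74, -0.25, -0.55, 0.16, 2.39 and -0.61 in that order, and in the overexpressor 0.28, 0.21, -0.14, -0.00, 1.82 and -0.11. The senescence call was lost without overexpressor salt replicate 1 (adjusted p = 0.216, over all alternatives 0.000311 to 0.895). The ethylene call was lost without wild-type mock replicate 1 (0.280) or 2 (0.0719), wild-type salt replicate 3 (0.287), overexpressor mock replicate 2 (0.0916) or 3 (0.142), overexpressor salt replicate 1 (0.386), and with the factors of DESeq2 (0.0511), with a range over all alternatives of 0.00376 to 0.899.

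Over the genes that salt changed in wild type, the salt response was smaller in the overexpressor, and whether the 6 lists follow from this was not tested. At equal depth the median overexpressor effect in salt of genes raised by salt in wild type was -0.294. Random thinning leaves a median fold change nearly unchanged, so this value was largely fixed in advance and is no evidence on depth. Leaving out 1 salt library gave at weakest -0.256. Choosing the raised genes in the overexpressor by itself moves its effect down in mock and up in salt. Yet their medians were 0.0703 in mock (0.0309 to 0.135 without 1 library) and -0.115 in salt (-0.197 to -0.0458). For these genes the signs argue against selection in wild type as the whole source. They also argue against a batch that shifted each gene by the same amount in all overexpressor libraries. A batch that shrank differences among all overexpressor libraries would give the same signs and stays open. No unchanged groups were simulated for genes chosen this way, so how far these medians vary without an effect is not known. An effect of ERF34 and any other difference between line #1 and wild type remain open, because only this overexpressor line was sequenced. Also open are a batch that touched the overexpressor salt libraries alone and a milder or later exposure of those leaves. Genotype and library number cannot be told apart. A weaker salt response through ERF34 may therefore be stated only as a hypothesis.

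A second pattern was a set of 7 genes called lower in the overexpressor in both conditions, MRD1, AT1G53490, AT2G01422, AT2G07080, QQS, AT3G60170 and AT5G24240. AT5G41660, at 0 counts in all 6 overexpressor libraries and 3.04 to 15.6 CPM in the wild-type ones, was called in salt but not in mock (adjusted p = 0.103). Of their 14 nearest tested neighbours, 14.3% were below a log2 fold change of -1 in both conditions, namely the overlapping pair of MRD1 and AT1G53490 counted for each other, which argues against loss or silencing of whole chromosome segments. A difference between the seed stocks, silencing of single genes and an effect of ERF34 were not tested. These genes were chosen for being lower with and without salt, and ERF34 was itself higher in both conditions. That pattern therefore cannot separate a standing difference between the lines from an effect of ERF34.

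The third pattern was that libraries of the same replicate number deviated together, with 1097 of 18886 genes showing an effect of the number. The clock list stood at percentile 96.1 and the jasmonate list at percentile 99.6 of 10000 matched random lists, values that time of day at harvest and handling of the leaves would give. However, 8 of the 24 lists stood at or above the 95th percentile, so neither source is singled out, and a shared day of growth or harvest may also be involved.

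For the pairwise comparisons, 3 against 3 makes 10 splits, too few for a share under 0.05. For salt in wild type 1 of the 10 splits, the real one, gave as many genes (6713 called, highest other 0), and for salt in the overexpressor also 1 (2227, highest other 0). For the overexpressor against wild type it was 2 in mock (4, highest other 216) and 1 in salt (13, highest other 0). The mock split with 216 genes set wild-type replicate 1 with overexpressor replicates 1 and 3 against the rest, which points to a structure of the samples. With the block in the 2 mock groups, 372 genes were called. For the interaction the real count was 0 genes by edgeR (2580 at an unadjusted p under 0.05, 658 by DESeq2, 64 by limma, 99 with a block within each genotype), so all 100 of 100 splits had to give at least as many and this comparison tests nothing. The highest other gave 695.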

How the results depend on the processing

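Counts thinned to equal depth, the block with only 2 groups, the block within each genotype, the block for the similarity and the left-out libraries for medians of salt genes were chosen only after the results were seen.

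Salt in wild type called 9650 genes with the replicate block, 6713 with only the 2 groups and 8469 with the block in 2 groups. It called 5921 to 7628 genes without 1 library and 3787 at an absolute log2 fold change of at least 1. Salt in the overexpressor called 1627 at that threshold, 5327 with the replicate block, 2227 with only the 2 groups, 2163 with the block in 2 groups, and 1519 (without mock replicate 1) to 2836 without 1 library. Other libraries that moved it were mock replicate 3 (1628) and salt replicate 2 (2116). The overexpressor against wild type in mock called 196 genes by DESeq2, 29 by limma, 4 with only the 2 groups and 372 with the block in 2 groups. It called 3 without wild-type replicate 1 or overexpressor replicate 1 or 3, 4 without wild-type replicate 2 or 3, and 11 without overexpressor replicate 2. In salt it called 428 at the fold threshold, 1763 by DESeq2, 2344 with the replicate block and 13 with only the 2 groups. Without 1 library it called 45 (wild-type replicate 3), 60 (wild-type replicate 2), 77 (overexpressor replicate 3), 347 (overexpressor replicate 2), 599 (overexpressor replicate 1) or 1017 (wild-type replicate 1). The interaction called 0 genes by edgeR (2580 at an unadjusted p under 0.05), 5 with the factors of DESeq2, 8 without a filter, 658 by DESeq2, 64 by limma, 379 with the replicate block, 99 with the block within each genotype, 6 with thinned counts, and 0 to 73 without 1 library (73 without overexpressor salt replicate 1, 67 without wild-type salt replicate 1, 36 without wild-type mock replicate 2, 6 without overexpressor mock replicate 2). Fitting only 2 groups leaves fewer libraries for the spread. For the rest the cause was not tested.

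The ERF34 difference in mock was log2 6.91 with only the 2 groups (adjusted p = 0.0820) and 7.05 with the block in 2 groups (adjusted p = 0.0526), where the call was lost (adjusted p over all alternatives 1.52e-44 to 0.0820). Without 1 library it was 6.48 to 7.39 in mock and 5.82 to 6.38 in salt, and called each time. Of the named calls, 54 of 70 for salt in wild type, 28 of 52 for salt in the overexpressor, 1 of 11 for genotype in mock (MRD1) and 5 of 16 for genotype in salt (ERF34, MRD1, AT2G01422, AT3G60170 and DIN2) held in every alternative. No named call reversed. In mock, 8, 7 and 7 of 11 named calls were lost without wild-type replicates 1, 2 and 3, and 8, 5 and 8 without overexpressor replicates 1, 2 and 3. In salt, 10 and 11 of 16 were lost without wild-type replicates 2 and 3, and 2, 6 and 10 without overexpressor replicates 1, 2 and 3.

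With an estimated correlation 0 lists were called by camera in each comparison, against 4, 5, 3, 7 and 6 with the preset one. With the replicate block the counts were 4, 3, 6, 6 and 6. Without 1 library they were 3 to 6, 3 to 6, 2 to 6, 6 to 9 and 5 to 7. Beside those given with the comparisons, lists were called without 1 library as follows. For salt in the overexpressor it was glucosinolates (0.0196) and anthocyanins (0.00150) without salt replicate 1. For genotype in mock, leaving out wild-type replicate 1 gave ion homeostasis (0.0491), senescence (0.0284) and jasmonate (4.08e-06), wild-type replicate 2 dehydration (0.0213), wild-type replicate 3 cell wall (0.0143) and vascular (0.00122), and overexpressor replicate 2 senescence (0.0381), chlorophyll synthesis (0.0211), jasmonate (7.55e-07) and vascular (0.0312). For genotype in salt, leaving out wild-type replicate 1 gave autophagy (0.0301), wild-type replicate 3 aquaporins and cell wall (0.0142 each), overexpressor replicate 1 cell wall (0.0198) and anthocyanins (0.00110), overexpressor replicate 2 autophagy (0.0275) and aquaporins (0.0321), and overexpressor replicate 3 autophagy (0.0101). For the interaction, jasmonate was called without wild-type mock replicate 2 (0.00527) or overexpressor mock replicate 1 (0.0271), the clock (0.0227) and anthocyanins (0.000845) without overexpressor salt replicate 1, and vascular without wild-type mock replicate 3 (0.0402). The cause was not tested. Between the genotypes in salt, where pairing was uncertain, the block ended the osmolyte call (adjusted p = 0.0650, over all alternatives 0.00838 to 0.805) and NAP was called (0.0393, over all alternatives 0.00461 to 0.192). Beside the calls given with the comparisons, the block changed no other call of a named gene or list.

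The similarity of the salt responses was 0.864 for genes of at least 10 CPM and 0.803 to 0.845 without 1 library. That of the overexpressor effects was -0.037 (without wild-type mock replicate 2) to 0.273 (without wild-type mock replicate 1). For genes raised by salt, the median overexpressor effect in mock and in salt was 0.209 and -0.505 at the fold threshold, and 0.0703 and -0.115 for genes chosen in the overexpressor. For genes lowered by salt it was -0.158 and 0.436, and -0.0905 and 0.125. Without 1 library the raised genes gave 0.0935 to 0.200 in mock and -0.345 to -0.256 in salt, and the lowered genes -0.161 to -0.0758 and 0.227 to 0.315. The cause was not tested.

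Thinning to equal depth moved the count from 829 to 681 for genotype in salt and from 7814 to 7335 for salt in wild type. In data simulated at the real depth and 3 libraries per group, edgeR recovered 22.2% of genes changed 2-fold for genotype in salt and 2.65% for the interaction, and DESeq2 41.3% and 15.3%, with at most 3, 4, 35 and 33 wrong calls in that order.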

Other observations

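The genes and lists in this part were chosen only after the results were seen.

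Salt raised 9 genes in wild type that it lowered in the overexpressor, and edgeR called 0 genes the other way round (328 and 387 for independent lists). CHX17, a cation/proton exchanger gene, went from 19.2 to 86.7 CPM in wild type and from 30.0 to 9.04 CPM in the overexpressor. EXT3, an extensin gene of the cell wall, went from 488 to 1017 CPM and from 552 to 275 CPM. The other genes were AT1G02360, RABA1e, AT5G50760, UCC2, AT3G18250, AT4G10510 and CYP71B6. Without a block, edgeR called the interaction for none of the 9 (adjusted p from 0.0530 to 0.0992). Their values with the replicate number as a block are not given here.

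The genes with the lowest interaction p were higher in wild-type salt than in overexpressor salt leaves. AT2G39530 was at 6.30, 35.3, 20.6 and 18.1 CPM in wild-type mock, wild-type salt, overexpressor mock and overexpressor salt, and AT3G51330 at 11.4, 68.3, 24.0 and 30.5 CPM. RABA1e, a small GTPase gene, was at 4.68, 11.6, 8.24 and 2.13 CPM.

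Anthocyanin and flavonoid genes were called lower as a list without overexpressor salt replicate 1, for salt in the overexpressor (adjusted p = 0.00150), between the genotypes in salt (0.00110) and for the interaction (0.000845), and not with all libraries (0.586, 0.998 and 0.746). Over all alternatives the adjusted p ran from these values to 0.961, 0.999 and 0.969. That library had the highest value of the 12 on the second principal component.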
